A study of Oncorhynchus kisutch with 48 samples.

How the data were processed

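Total RNA from gill, liver and olfactory rosette of 16 juvenile coho salmon (Oncorhynchus kisutch) was labelled with Cy3 and hybridised to 48 one-colour Agilent salmonid oligonucleotide arrays, 1 array per tissue and fish. The fish had been held in freshwater (control, under 0.5 ppth) or acclimated in steps to 8 ppth (low), 16 ppth (medium) or 32 ppth (high), and 4 fish of each salinity were sampled. A fish is named here by its group and the fish number in the labels. These sat on 12 slides of 4 arrays scanned on 3 days. Each of the 12 groups of tissue and salinity was spread over 4 slides, with 1 to 2 arrays on each scan day, and each slide held 1 to 2 arrays of a tissue, so neither slide nor scan day coincided with salinity.

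The authors extracted spot values with Agilent Feature Extraction 10.7.1.1. Per the file headers, the processed signal of each spot is an intensity on a linear scale, after background subtraction and detrending within the array and with no scaling between arrays, and signals that were not positive and significant were replaced by a surrogate value (13.9 to 51.1% of spots per array). Per the file headers, the mean spot signal and the median local background are intensity values as well, without background subtraction or scaling. The table of values deposited by the authors holds log2 values between 5.6762 and 18.8768 with column medians of 7.259 to 7.265, and the labels leave its normalization open. The scanner values of each of the 48 arrays ranked its spots most like its own column of that table (Spearman correlation 0.8943 to 0.996 across spots, which are not independent replicates).

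From the scanner files, log2 processed signal was scaled by subtracting the array's 75th percentile over all 43803 non-control spots. Spots of 1 probe were averaged (43603 distinct probes), and 2 to 63 spots per array were left out because the scanner software had marked them as non-uniform or as population outliers. A probe was tested in a tissue if it was well above background, by the scanner software's own call, on all 4 arrays of at least 1 of the tissue's 4 groups. This kept 25029 probes in gill, 17656 in liver and 27387 in rosette. Percentile scaling over all spots was fixed before the data were examined. Scaling over only the probes well above background on all 16 arrays of a tissue (14800 in gill, 9576 in liver, 23150 in rosette) was added as an alternative after it was seen that the mean share of spots detected on liver arrays was 47.4%.

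Each array reported 23.5 to 72.7% of its spots well above background, its median signal lay between 6.99 and 49.2 and its 75th percentile between 40.5 and 309. The mean share of spots well above background was 61.1 ± 10.5% in gill, 47.4 ± 11.2% in liver and 65.1 ± 4.2% in rosette (SD, n = 16 each). At most 1 spot on an array was saturated. With 4 arrays per group, the number of arrays limits the precision. Within the 12 groups, Pearson correlations between 2 arrays ran from 0.9291 to 0.9794 over 72 pairs, across probes, which are not independent replicates.

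Probe names came from the array annotation: 9026 probes carried a characterised gene name (3116 from a RefSeq record, 3224 from a GenBank mRNA, 2686 by similarity of a consensus sequence covering at least 20% of the matched protein), for 5852 distinct names. The other 34577 probes had no usable name and are counted but not described. The RefSeq accessions on the array (2365) come from other salmonids and 0 of them are in the coho gene table, which holds 365 of the 2158 distinct symbols, so no genome position is given. Many probes were designed on sequences of related salmonids, and how far a probe tells apart the duplicated genes of salmonids was not known.

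Within each tissue, limma 3.58.1 (lmFit, eBayes with an intensity trend) in R 4.3.3 fitted 1 mean per salinity to the 16 arrays (12 residual degrees of freedom). The contrasts were 8, 16 and 32 ppth against control, 32 against 8 ppth, and the slope on salinity in ppth, with control entered as 0.5. P-values were adjusted by Benjamini and Hochberg over the probes tested in that tissue and contrast, and a probe rose or fell when its adjusted p was under 0.05. Tissue differences in the 32 ppth response were tested as interaction contrasts in a pooled fit of all 48 arrays, with fish as a random block (correlation 0.0377 to 0.0426). The 3 tissues of a fish were matched by group and fish number in the labels. Over the 16 fish, deviations from group means correlated by a mean of 0.074 (-0.225 to 0.242) for gill and liver, 0.138 (-0.267 to 0.476) for gill and rosette and 0.159 (-0.261 to 0.319) for liver and rosette. Fold values are given with their standard error in log2 units. Where a gene was not well above background on any array of 1 group, its fold is given as "at least", computed against the higher of its measured level and the lowest signal called well above background on each of those arrays.

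Shifts of 31 gene lists, fixed before the data were examined together with the tests, were tested with limma's camera (preset correlation between genes of 0.01, 1 probe per gene, at least 5 measured genes), adjusted over all lists and the 9 contrasts against control. Membership was by name pattern, and after the array names were seen 85 false pattern matches were taken out and 9 genes under another spelling added, without sight of their values. Beside each list's result stands the adjusted p with an estimated correlation, and each count of members past the limit over all probes is given with that adjusted over the list alone.

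Genes named in the text were chosen by a rule fixed before the data were examined. Among probes that passed, carried 1 characterised gene name and had all 4 exposed arrays on 1 side of all 4 control arrays, it takes the 10 largest rises and 10 largest falls at 32 ppth, the 4 largest at 8 and at 16 ppth, and the 3 largest in each direction for each difference between tissues. It adds up to 4 members of each list with the smallest p. In gill it adds, whatever their result, Na/K-ATPase alpha and beta, the Na/K/2Cl co-transporter, CFTR, V-type H-ATPase, carbonic anhydrase, Na/H exchanger and FXYD, each as the probe with the highest mean, with the behaviour of the family's other probes. The Na/Cl co-transporter had no probe. How this last clause was read was settled after a first table of alternatives had been seen. With each family member followed separately, 49 further values of 24 genes reversed sign under an alternative, 0 of them for a gene that had passed. One name of a cDNA clone was taken off the list of names after the list had been seen.

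Alternatives were other scalings (quantile normalization, normexp with an offset of 50, the authors' table), other filters, array weights, no intensity trend, slide as a random or fixed block, the fish number as block, a fit of all 48 arrays, only the 8 arrays compared, a minimum change of 1.5-fold, 1 value per gene, and leaving out each array in turn. Scan day as a block, scaling over detected probes, leaving out arrays with under 40% of spots well above background, and leaving out probes at least 16-fold brighter on the liver arrays than in the tissue tested were added after the data were seen. Other splits of the arrays compared (35 splits of 8, or 100 drawn relabellings) were run for each count. On simulated arrays with known changes, in the gill contrast of 32 ppth against control, the pipeline recovered 5.97% of 1.5-fold, 38.8% of 2-fold and 80.3% of 4-fold changes, with 4 false calls among 25029 probes. It found 50 of 50 shifted lists in each tissue. Tables were made with data.table (1.17.8), numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9 (Python 3.11.15).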

Results

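Transcript levels were measured on 48 arrays, 1 for each of 3 tissues of 16 juvenile coho salmon, with 4 fish in freshwater control and 4 each at 8, 16 and 32 ppth. The comparisons ask how acclimation to rising salinity changed transcript levels in gill, liver and olfactory rosette, the sheet of sensory epithelium in the nose. Values are log2 signal relative to the array's 75th percentile, changes are log2 differences from control ± SE with n = 4 arrays per group, and p-values are limma's, adjusted over all probes tested. Arrays reported 23.5 to 72.7% of their spots well above background, and 1 gill and 3 liver arrays lay under 40%. Of the gene lists, cartilage and bone, circadian clock, exocrine pancreas and estrogen-responsive egg proteins had under 5 measured genes and were not tested, and neuron markers were not tested in liver.

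In gill at 32 ppth, the chloride channel CFTR I rose by 4.44 ± 0.34 (21.8-fold, adjusted p = 4.57e-06), against 1.77 in the authors' table and 2.33 by normexp with quantile normalization, and the Na/K/2Cl co-transporter, which brings chloride into secreting cells, rose by 2 ± 0.24 (adjusted p = 0.000458). The alpha subunits of the Na/K-ATPase, the pump that drives ion transport, went opposite ways. Isoform 1b rose by 1.81 ± 0.19 (adjusted p = 0.000121), and isoform 1a, from a level of 9.89 ± 0.53 (SD) in control to 6.72 ± 0.34, fell, with a change of -3.17 ± 0.26 (9.01-fold, adjusted p = 6.36e-06). The second CFTR gene, CFTR II, did not pass (0.59 ± 0.22, adjusted p = 0.383). None of the 9 probes of FXYD regulators passed, nor the Na/K-ATPase subunits beta-233 (0.93 ± 0.45, adjusted p = 0.536) and beta 3b, nor carbonic anhydrase 12 (1.47 ± 0.32, adjusted p = 0.0554) and the other 3 carbonic anhydrase probes, nor Na/H exchanger 8 (-0.88 ± 0.35, adjusted p = 0.424). Of 22 probes of the vacuolar proton pump, 1 passed, for subunit D, which rose by 0.74 ± 0.1 (adjusted p = 0.00225).

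**Figure D1:**
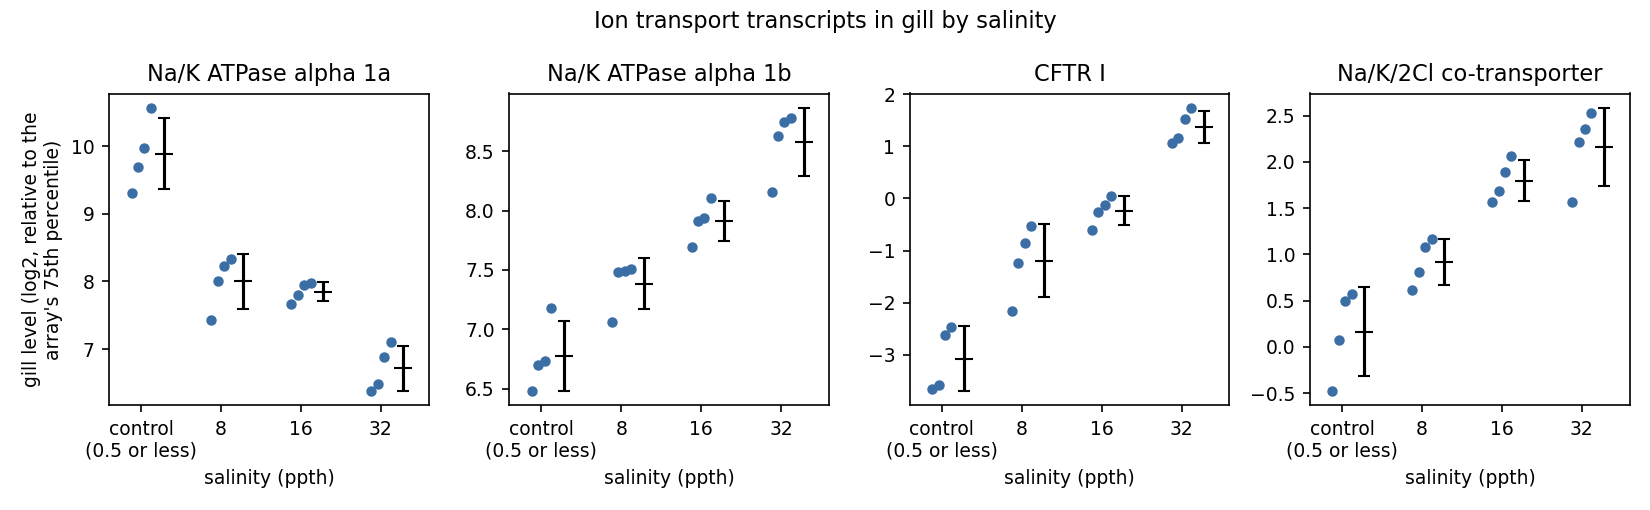
Log2 signal in gill, relative to each array's 75th percentile, against salinity in ppth for 4 ion transport genes. Points are the 4 arrays of each salinity with their mean and SD, and CFTR I, isoform 1b of the Na/K-ATPase alpha subunit and the Na/K/2Cl co-transporter are higher at 32 ppth while isoform 1a is lower.

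Further rises in gill at 32 ppth were RTP801, an inhibitor of growth signalling (2.16 ± 0.44), dynein light intermediate chain 1 (2.11 ± 0.41), RGS1, which shortens G-protein signals (1.99 ± 0.27), transmembrane protein 59 (1.77 ± 0.28), TSC22D3, a transcription regulator induced by glucocorticoids (1.5 ± 0.28), and guanylate-binding protein 1 (1.3 ± 0.24). Preproinsulin 2, the precursor of insulin, was well above background on 4 of 4 arrays at 32 ppth and on none of the 4 control arrays, and was at least 19.5-fold higher by the percentile scaling, with a change of 1.8 by normexp with quantile normalization and 1.22 in the authors' table. The falls included the ubiquitin ligase RNF128 (-3.11 ± 0.43), RASD1, a small G protein (-2.07 ± 0.17), the phosphatase phospho1 (-1.98 ± 0.3), ornithine decarboxylase 1, the first enzyme of polyamine synthesis (-1.73 ± 0.16), and glycogenin-1, which primes glycogen synthesis (-1.71 ± 0.22). Collagen X (-1.56 ± 0.26), cytochrome P450 7B1 (-1.53 ± 0.22), LBH (-1.33 ± 0.21) and DNA polymerase subunit delta-4 (-1.32 ± 0.24) also fell. A further probe had the opposite sign for RASD1, guanylate-binding protein 1 and cytochrome P450 7B1, as did 2 for glycogenin-1.

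By list, seawater ion secretion was shifted up at 32 ppth in gill (17 genes, adjusted p = 0.000408). For seawater ion secretion p was 7.95e-05 to 0.097 over alternatives (adjusted p = 0.097 with estimated correlation). Of its members 3 rose and 1, isoform 1a, fell, and 6 rose and 1 fell adjusted over the list alone. Interferon response was shifted up (19 genes, adjusted p = 0.000304), with rises of interferon regulatory factor 1 (1.09 ± 0.17) and guanylate-binding protein 1, the 2 also adjusted over the list alone. For interferon response p was 0.00019 to 0.119 over alternatives (adjusted p = 0.119 with estimated correlation). Freshwater ion uptake was shifted up (19 genes, adjusted p = 0.00247), with 5 rises adjusted over the list alone. Its p was 0.000565 to 0.119 over alternatives (0.119 with estimated correlation). Only subunit D passed, of the vacuolar pump (13 genes in gill), which acidifies compartments and cell surfaces, so the shift may not be uptake. Lymphocyte and myeloid markers, which belong to blood and immune cells, were shifted up (28 genes, adjusted p = 0.00647), while the 1 member that passed, the chemokine CCL20, fell (-0.83 ± 0.14), also adjusted over the list alone. For lymphocyte and myeloid markers p was 0.000116 to 0.277 over alternatives (adjusted p = 0.277 with estimated correlation). The glucocorticoid-responsive list was shifted up (5 genes, adjusted p = 0.0307), with TSC22D3 past the limit and 2 rises adjusted over the list alone, and its adjusted p was 0.0616 with scan day as a block. For glucocorticoid-responsive genes p was 0.0145 to 0.282 over alternatives (adjusted p = 0.282 with estimated correlation). The proteasome list was shifted up (20 genes, adjusted p = 0.0328), with 0 members past the limit in either count and an adjusted p of 0.142 without the dim arrays. For proteasome p was 0.00851 to 0.727 over alternatives (adjusted p = 0.727 with estimated correlation).

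In gill at 32 ppth 119 of 25029 probes passed, 67 up and 52 down, for 41 named genes. With slide as a fixed block in the fit of 48 arrays 65 passed, and 40 (17 up, 23 down) in a fit of the 8 arrays compared.

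In gill at 8 ppth, CFTR I rose by 1.88 ± 0.34 and isoform 1a of the Na/K-ATPase alpha subunit fell, with a change of -1.89 ± 0.26. Isoform 1b (0.62 ± 0.19, adjusted p = 0.13), the Na/K/2Cl co-transporter (0.75 ± 0.24, adjusted p = 0.146) and CFTR II (0.02 ± 0.22, adjusted p = 0.983) did not pass. The chemokine SCYA113 (1.64 ± 0.33), an osteopontin-like matrix protein (1.28 ± 0.27) and the ribosome assembly factor NIP7 (1.2 ± 0.23) rose. The phosphatase phospho1 (-2.32 ± 0.3), RNF128 (-2.06 ± 0.43) and the proteasome subunit PSMD1 (-1.51 ± 0.3) fell. None of the probes of Na/K-ATPase beta, FXYD, vacuolar pump, carbonic anhydrase or Na/H exchanger passed.

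The oxidative phosphorylation list, the mitochondrial machinery that makes ATP, was shifted down at 8 ppth in gill (43 genes, adjusted p = 4.46e-10). For oxidative phosphorylation p was 3.96e-12 to 0.097 over alternatives (adjusted p = 0.097 with estimated correlation). Its 5 falls were ATP synthase F1 beta, on the probes named atp5b (-1.47 ± 0.22) and ATP synthase subunit beta (-1.1 ± 0.21), ATP synthase subunit C3 (-1.09 ± 0.18) and the NADH dehydrogenase subunits NDUFS8 (-0.79 ± 0.14) and NDUFA5 (-0.62 ± 0.12), and 20 fell and 1 rose adjusted over the list alone. Gluconeogenesis and amino acid catabolism was shifted down (15 genes, adjusted p = 0.00398), with a fall of mitochondrial aspartate aminotransferase (-0.85 ± 0.16) and 3 falls adjusted over the list alone. For gluconeogenesis and amino acid catabolism p was 0.00149 to 0.119 over alternatives (adjusted p = 0.119 with estimated correlation). Glycolysis was shifted down (19 genes, adjusted p = 0.00647), with a fall of muscle pyruvate kinase (-1.1 ± 0.23), 6 falls adjusted over the list alone, and an adjusted p of 0.146 without the dim arrays. For glycolysis p was 0.00193 to 0.445 over alternatives (adjusted p = 0.445 with estimated correlation). Cholesterol synthesis was shifted down (5 genes, adjusted p = 0.0491), with 0 members past the limit, 1 fall adjusted over the list alone, and an adjusted p of 0.0604 with scan day as a block. For cholesterol synthesis p was 0.0176 to 0.277 over alternatives (adjusted p = 0.277 with estimated correlation). Beside them, hepatocyte markers were lower (7 genes, adjusted p = 0.0209) and muscle markers higher (17 genes, adjusted p = 0.0332), each with 0 members past the limit, and 2 muscle markers rose adjusted over the list alone. For hepatocyte markers p was 0.000253 to 0.445 over alternatives (adjusted p = 0.445 with estimated correlation). For muscle markers p was 0.00431 to 0.602 over alternatives (adjusted p = 0.602 with estimated correlation).

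In gill at 8 ppth 176 probes passed, 45 up and 131 down, for 72 named genes. The balance depended on the scaling, with 96 up and 118 down by quantile normalization, 139 and 142 in the authors' table and 155 and 133 with the percentile over detected probes. Without the dim control array 57 passed (26 up, 31 down), and 2 in a fit of the 8 arrays.

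In gill at 16 ppth, CFTR I (2.84 ± 0.34), the Na/K/2Cl co-transporter (1.63 ± 0.24), isoform 1b of the alpha subunit (1.14 ± 0.19), RGS1 (2.31 ± 0.27) and TSC22D3 (1.53 ± 0.28) rose. Isoform 1a (-2.04 ± 0.26), RNF128 (-3.05 ± 0.43), phospho1 (-1.99 ± 0.3) and RASD1 (-1.52 ± 0.17) fell. Interferon response was shifted up (19 genes, adjusted p = 0.00277) with 0 members past the limit in either count. For interferon response p was 0.00192 to 0.2 over alternatives (adjusted p = 0.2 with estimated correlation). Lymphocyte and myeloid markers were shifted up (28 genes, adjusted p = 0.00647), while CCL20, the member that passed, fell (-0.88 ± 0.14), and 2 rose and 2 fell adjusted over the list alone. For lymphocyte and myeloid markers p was 0.000293 to 0.277 over alternatives (adjusted p = 0.277 with estimated correlation). Ribosomal proteins were shifted up (72 genes, adjusted p = 0.0332), with 0 members past the limit and 1 rise adjusted over the list alone. For ribosomal proteins p was 3.04e-05 to 0.892 over alternatives (adjusted p = 0.727 with estimated correlation). In all 44 probes passed, 18 up and 26 down, for 15 named genes. With slide as a fixed block 15 passed, and 14 in a fit of the 8 arrays.

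Between 8 and 32 ppth in gill, CFTR I was higher at 32 ppth by 2.56 ± 0.34 (adjusted p = 0.00257), the Na/K/2Cl co-transporter by 1.25 ± 0.24 (adjusted p = 0.0245) and isoform 1b by 1.19 ± 0.19 (adjusted p = 0.00974). Isoform 1a differed by -1.28 ± 0.26 (adjusted p = 0.0328), ornithine decarboxylase 1 by -1.02 ± 0.16 and glycogenin-1 by -1.06 ± 0.22, all lower at 32 ppth. In this contrast the vacuolar pump subunits D (0.75 ± 0.1) and E 1 (1.06 ± 0.2) and FXYD 6 (1.47 ± 0.28) were higher at 32 ppth. Along salinity, CFTR I rose by 1.34 ± 0.12 per 10 ppth, the Na/K/2Cl co-transporter by 0.63 ± 0.09, isoform 1b by 0.56 ± 0.06 and carbonic anhydrase 12 by 0.48 ± 0.1, and the slope of isoform 1a was -0.9 ± 0.12. Between 8 and 32 ppth 228 probes passed, 125 up and 103 down, against 115 and 149 in the authors' table, 114 and 160 with the percentile over detected probes, 50 and 64 with slide as a fixed block and 62 and 68 with scan day as a block. The trend passed for 69 probes, 44 up and 25 down, against 63 and 22 in the authors' table.

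In gill, the lists for acute phase and complement, antioxidant defence, cell cycle, collagen and extracellular matrix, erythrocyte markers, fatty acid and lipid metabolism (lowest adjusted p 0.092, at 8 ppth), heat shock, hormone receptors and IGF axis, keratins and mucus, neuron markers, olfactory signalling, osmotic stress, tight junctions and xenobiotic metabolism did not pass at any salinity.

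In liver at 8 ppth, hypoxia up-regulated protein 1 (2.17 ± 0.43) and calumenin (2.03 ± 0.4), both of the endoplasmic reticulum, rose, with protein-arginine deiminase 2 (1.8 ± 0.35), the coat protein zeta2-COP (1.55 ± 0.25) and the chaperone heat shock cognate 71 (1.33 ± 0.23). Mid1-interacting protein 1, a regulator of fatty acid synthesis (-4.22 ± 0.82), VEGF-D (-2.09 ± 0.38), protein kinase C substrate 80K-H (-1.29 ± 0.2) and Xaa-Pro aminopeptidase 1 (-1.22 ± 0.23) fell. Heat shock and unfolded protein response was shifted up (29 genes, adjusted p = 0.0117), with 3 rises adjusted over the list alone and an adjusted p of 0.0576 with scan day as a block. For heat shock and unfolded protein response p was 0.00512 to 0.406 over alternatives (adjusted p = 0.406 with estimated correlation). Ribosomal proteins were shifted up (66 genes, adjusted p = 0.00267), with 0 members past the limit and 2 rises adjusted over the list alone. For ribosomal proteins p was 3.87e-05 to 0.687 over alternatives (adjusted p = 0.687 with estimated correlation). Xenobiotic metabolism (26 genes, adjusted p = 0.000531) and gluconeogenesis and amino acid catabolism (15 genes, adjusted p = 0.00122) were shifted down, with 0 members past the limit in each and 5 and 1 falls adjusted over the list alone. For xenobiotic metabolism p was 6.14e-05 to 0.406 over alternatives (adjusted p = 0.406 with estimated correlation). For gluconeogenesis and amino acid catabolism p was 0.000123 to 0.277 over alternatives (adjusted p = 0.277 with estimated correlation). In all 36 probes passed, 27 up and 9 down, for 16 named genes. None passed with limma and scan day as a block, in a fit of the 8 arrays or without any 1 of 9 arrays (2134 at unadjusted p under 0.05 in the fit reported), while 63 passed (49 up, 14 down) without the dim arrays, 928 in the fit of 48 arrays and 1126 there with slide as a fixed block. The split was 20 up and 13 down by quantile normalization and 25 and 18 with the percentile over detected probes.

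In liver at 16 ppth, the amino acid transporter SLC38A2 (1.62 ± 0.22), which also passed on its other probe, calpain 1 (1.69 ± 0.35), the kinase Pim-1 (1.46 ± 0.25) and the phosphatase SSU72 (1.41 ± 0.29) rose. Mid1-interacting protein 1 (-4.65 ± 0.82), the coactivator p15 (-1.99 ± 0.37), F10 protein (-1.43 ± 0.29) and short-chain acyl-CoA dehydrogenase, an enzyme of fatty acid oxidation (-1.35 ± 0.28), fell. Of the lists, interferon response was shifted down (12 genes, adjusted p = 0.00732), as was gluconeogenesis and amino acid catabolism (15 genes, adjusted p = 0.0255), each with 2 falls adjusted over the list alone. For interferon response p was 0.00522 to 0.282 over alternatives (adjusted p = 0.282 with estimated correlation). For gluconeogenesis and amino acid catabolism p was 0.0052 to 0.445 over alternatives (adjusted p = 0.445 with estimated correlation). Osmotic stress and osmolytes was shifted up (8 genes, adjusted p = 0.0304), with 2 rises adjusted over the list alone and an adjusted p of 0.0604 with scan day as a block and 0.0963 without the dim arrays. For osmotic stress and osmolytes p was 0.012 to 0.445 over alternatives (adjusted p = 0.445 with estimated correlation). Beside them, erythrocyte markers were lower (6 genes, adjusted p = 0.00803), with 3 falls adjusted over the list alone and an adjusted p of 0.0598 without the dim arrays, and 0 members of these 4 lists passed over all probes. For erythrocyte markers p was 0.00247 to 0.333 over alternatives (adjusted p = 0.333 with estimated correlation). In all 72 probes passed, 45 up and 27 down, for 25 named genes. None passed in a fit of the 8 arrays (limma, 2587 at unadjusted p under 0.05 in the fit reported), against 1227 in the fit of 48 arrays and 275 there with slide as a fixed block.

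In liver at 32 ppth, SLC38A2 rose (1.58 ± 0.22). Chemotaxin (-2.1 ± 0.37), RNF128 (-1.67 ± 0.22), integral membrane protein 2C (-1.48 ± 0.27), the growth factor precursor granulin (-1.48 ± 0.2), the RNA-binding protein CPEB4 (-1.29 ± 0.23), protein kinase C substrate 80K-H (-1.26 ± 0.2) and calpastatin, an inhibitor of calpains (-1.15 ± 0.22), fell. Glucocorticoid-responsive genes were shifted up (7 genes, adjusted p = 0.00483), with 3 rises adjusted over the list alone and an adjusted p of 0.084 without the dim arrays. For glucocorticoid-responsive genes p was 0.000388 to 0.224 over alternatives (adjusted p = 0.224 with estimated correlation). Acute phase and complement (18 genes, adjusted p = 0.0117), gluconeogenesis and amino acid catabolism (15 genes, adjusted p = 0.0316) and xenobiotic metabolism (26 genes, adjusted p = 0.0372) were shifted down, with 5, 2 and 2 falls adjusted over the list alone. For acute phase and complement p was 0.00474 to 0.224 over alternatives (adjusted p = 0.224 with estimated correlation). For gluconeogenesis and amino acid catabolism p was 0.0193 to 0.445 over alternatives (adjusted p = 0.445 with estimated correlation). For xenobiotic metabolism p was 0.00512 to 0.657 over alternatives (adjusted p = 0.657 with estimated correlation). Beside them, erythrocyte markers were lower (6 genes, adjusted p = 0.0438), with 1 fall adjusted over the list alone. For erythrocyte markers p was 0.0113 to 0.445 over alternatives (adjusted p = 0.445 with estimated correlation). With scan day as a block the adjusted p was 0.0636 for xenobiotic metabolism and 0.0616 for erythrocyte markers, which had 0.248 without the dim arrays, and 0 members of these 5 lists passed over all probes.

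In liver at 32 ppth 28 probes passed, 6 up and 22 down, for 9 named genes. The split was 10 up and 17 down by quantile normalization, 8 and 14 in the authors' table and 12 and 16 with the percentile over detected probes. Without the dim arrays 9 passed, and 0 in a fit of the 8 arrays (limma, 2321 at unadjusted p under 0.05 in the fit reported), against 776 in the fit of 48 arrays and 336 there with slide as a fixed block. Between 8 and 32 ppth, where the median change of all probes was -0.112, 4 probes passed. All were lower at 32 ppth and are named after their values were seen: chemotaxin (-2.62 ± 0.374) and the unnamed probes A_05_P429502 (-2.82 ± 0.378), A_05_P445112 (-1.2 ± 0.184) and A_05_P474517 (-2.1 ± 0.302). None passed there with scan day as a block or without the dim arrays (limma, 2198 at unadjusted p under 0.05 in the fit reported), against 720 in the fit of 48 arrays and 436 with slide. The trend passed for 0 probes with limma (2193 at unadjusted p under 0.05), for 16 with the order of the groups in place of ppth, for 556 (128 up, 428 down) in the fit of 48 arrays and for 67 (19 up, 48 down) there with slide as a fixed block. Liver lists that did not pass at any salinity were antioxidant defence, cell cycle, cholesterol synthesis, collagen and extracellular matrix, fatty acid and lipid metabolism, freshwater ion uptake, glycolysis (lowest adjusted p 0.0707, at 16 ppth), hepatocyte markers, hormone receptors and IGF axis, keratins and mucus, lymphocyte and myeloid markers, muscle markers, olfactory signalling, oxidative phosphorylation, proteasome, seawater ion secretion and tight junctions.

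In the olfactory rosette at 32 ppth, the largest falls were mostly of transcripts known for their abundance in liver. These were liver-type fatty acid-binding protein (-5.78 ± 0.95), secreted phosphoprotein 24 (-5.5 ± 0.84), the plasma proteins plasminogen (at least 12.2-fold), antithrombin (at least 12-fold) and fibrinogen gamma (-4.77 ± 0.81), C1 inhibitor (-4.34 ± 0.59), the iron carrier transferrin (-4.15 ± 0.86) and formimidoyltransferase-cyclodeaminase (at least 4.03-fold). The bounds hold for the percentile scaling only, and in the authors' table plasminogen (-0.77), antithrombin (-0.73) and formimidoyltransferase-cyclodeaminase (-0.3) did not pass. Pentraxin (-3.5 ± 0.5) and C-type lectin receptor B (-3.35 ± 0.71) also fell. ADP-ribosylation factor 4, of vesicle traffic (2.69 ± 0.49), the coactivator ASCC1 (2.2 ± 0.36), TSC22D3 (1.74 ± 0.36), very long-chain acyl-CoA synthetase (1.34 ± 0.16), the NEDD8-conjugating enzyme Ubc12 (0.87 ± 0.16) and catenin beta-1 (0.72 ± 0.12) rose, and CFTR I was at least 1.55-fold higher (0.11 in the authors' table). Brain protein I3 (0.71 ± 0.15), gastrulation-specific protein G12 (0.71 ± 0.15) and Hermansky-Pudlak syndrome 4 protein (0.61 ± 0.13) rose as well. For ADP-ribosylation factor 4, 2 of 5 further probes had the opposite sign and 0 of the 5 passed in the same direction.

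Hepatocyte markers were lower in the rosette at 32 ppth (8 genes, adjusted p = 9.89e-09), with 4 falls (prothrombin, antithrombin on 2 gene names and transferrin) and 6 adjusted over the list alone. For hepatocyte markers p was 1.97e-11 to 0.224 over alternatives (adjusted p = 0.224 with estimated correlation). Acute phase and complement was shifted down (19 genes, adjusted p = 0.0263), with falls of complement factor H (-3.32 ± 0.57), C9 (-2.47 ± 0.46) and factor B (-2.45 ± 0.47), which are secreted mainly by liver, and 4 falls adjusted over the list alone. For acute phase and complement p was 0.00372 to 0.526 over alternatives (adjusted p = 0.526 with estimated correlation). Xenobiotic metabolism was shifted down (27 genes, adjusted p = 0.0096), with a fall of cytochrome P450 1A1 (-1.42 ± 0.3) and 6 falls adjusted over the list alone. For xenobiotic metabolism p was 0.00189 to 0.39 over alternatives (adjusted p = 0.39 with estimated correlation). Lymphocyte and myeloid markers were lower (28 genes, adjusted p = 5.03e-05), with a fall of the chemokine receptor CCR6 (-1.36 ± 0.24) and 3 adjusted over the list alone. For lymphocyte and myeloid markers p was 7.13e-06 to 0.176 over alternatives (adjusted p = 0.176 with estimated correlation). Neuron markers were higher (10 genes, adjusted p = 0.0307), with 0 members past the limit in either count. For neuron markers p was 0.00275 to 0.559 over alternatives (adjusted p = 0.559 with estimated correlation). In all 133 probes passed, 41 up and 92 down, for 35 named genes. Of the 92 falls, 68 were of probes at least 16-fold brighter on the liver arrays, and without such probes 18 passed (12 up, 6 down). Of all 711 such probes, 427 were lower, with a median change of -0.1. The count was 86 with scan day as a block, 74 with slide as a fixed block, 75 by normexp with quantile normalization and 52 in the authors' table.

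**Figure D2:**
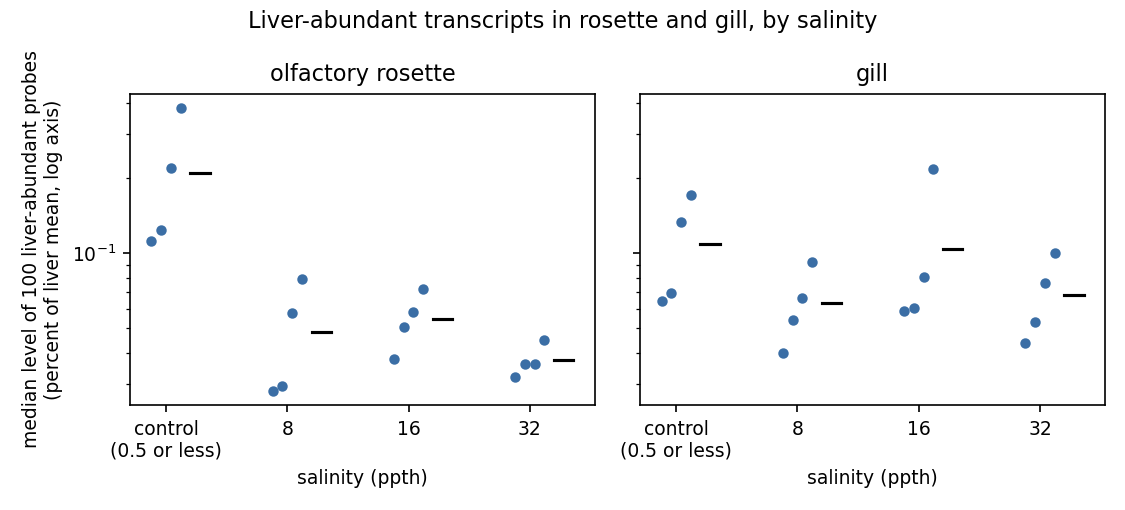
Median level of the 100 most liver-abundant probes on each olfactory rosette and gill array, in percent of their mean level in liver on a log axis, by salinity in ppth, with points for the 4 arrays of each group and a line at their mean. In the rosette the mean is 0.21% in control and 0.0373% at 32 ppth, and in gill 0.109% and 0.0682%.

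In the rosette at 8 ppth, liver-type fatty acid-binding protein (-5.46 ± 0.95), secreted phosphoprotein 24 (-4.89 ± 0.84), antithrombin (-4.11 ± 0.89) and transferrin (-4.09 ± 0.86) had the largest falls. RNA-binding protein 39 (at least 1.49-fold), 2,5-diketo-D-gluconic acid reductase (at least 2.45-fold), Purkinje cell protein 4-like 1 (1.78 ± 0.38) and the chaperone HSP 90-alpha (1.49 ± 0.27) rose. In the authors' table RNA-binding protein 39 (0.07) and the reductase (0.17) did not pass. Glycolysis, the pathway from glucose to pyruvate, was shifted down (20 genes, adjusted p = 0.00122), and its 6 falls were glucose-6-phosphate isomerase (-0.93 ± 0.16), aldolase B (-1.24 ± 0.29), glyceraldehyde-3-phosphate dehydrogenase (-0.79 ± 0.2), phosphoglycerate kinase 1 (-0.88 ± 0.16), phosphoglycerate mutase 1 and alpha-enolase (-1.11 ± 0.23), with 7 falls and 1 rise adjusted over the list alone. For glycolysis p was 0.000248 to 0.406 over alternatives (adjusted p = 0.406 with estimated correlation). Gluconeogenesis and amino acid catabolism was shifted down (16 genes, adjusted p = 0.00147), with falls of 4-hydroxyphenylpyruvate dioxygenase and mitochondrial aspartate aminotransferase and 4 adjusted over the list alone. For gluconeogenesis and amino acid catabolism p was 0.000436 to 0.224 over alternatives (adjusted p = 0.224 with estimated correlation). Cell cycle was shifted down (14 genes, adjusted p = 0.00512), with falls of the replication protein MCM7 (-0.54 ± 0.13) and thymidylate synthase (-0.89 ± 0.23) and 4 adjusted over the list alone. For cell cycle p was 0.0027 to 0.406 over alternatives (adjusted p = 0.406 with estimated correlation). Freshwater ion uptake was shifted up (20 genes, adjusted p = 0.0263), with rises of vacuolar pump subunit A (0.75 ± 0.12) and carbonic anhydrase 12 (1.18 ± 0.25), a fall of vacuolar pump subunit a (-0.85 ± 0.19), and 6 rises and 1 fall adjusted over the list alone. For freshwater ion uptake p was 0.00546 to 0.277 over alternatives (adjusted p = 0.277 with estimated correlation).

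Also in the rosette at 8 ppth, hepatocyte markers were lower (8 genes, adjusted p = 5.38e-06), with 4 falls over all probes and 6 adjusted over the list alone, and acute phase and complement was lower (19 genes, adjusted p = 0.00267), with falls of complement factor H and C9 and 4 adjusted over the list alone. For hepatocyte markers p was 1.25e-08 to 0.277 over alternatives (adjusted p = 0.277 with estimated correlation). For acute phase and complement p was 2.25e-05 to 0.406 over alternatives (adjusted p = 0.406 with estimated correlation). Lymphocyte and myeloid markers were lower (28 genes, adjusted p = 5.03e-05), with falls of the T-cell kinase LCK (-0.96 ± 0.19), the chemokine receptor CCR3, the chemokine CCL19 and the G-CSF receptor (-0.96 ± 0.24), and 9 adjusted over the list alone. For lymphocyte and myeloid markers p was 1.22e-06 to 0.176 over alternatives (adjusted p = 0.176 with estimated correlation). Interferon response was lower (18 genes, adjusted p = 0.0304), with 0 members past the limit in either count. For interferon response p was 0.011 to 0.406 over alternatives (adjusted p = 0.406 with estimated correlation). Keratins and mucus was lower (13 genes, adjusted p = 0.0361), with a fall of type II keratin E1 (-1.28 ± 0.23), also adjusted over the list alone. For keratins and mucus p was 0.00841 to 0.602 over alternatives (adjusted p = 0.602 with estimated correlation). In all 1045 probes passed, 546 up and 499 down, for 292 named genes. Of the 499 falls 91 were of probes at least 16-fold brighter on the liver arrays. Of all 711 such probes, 459 were lower (median change -0.17). The count was 178 (53 up, 125 down) in the fit of 48 arrays, 241 (50 up, 191 down) there with slide as a fixed block, 3397 with slide as a random block and 0 in a fit of the 8 arrays (limma, 5591 at unadjusted p under 0.05 in the fit reported).

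In the rosette at 16 ppth, ADP-ribosylation factor 4 (3.03 ± 0.49), the cap-binding protein eIF4E type 2 (2.04 ± 0.4), the kinase EIF2AK1 (at least 1.08-fold, but 0.06 and not past the limit in the authors' table) and a copper amine oxidase (1.14 ± 0.22) rose. C-type lectin receptor B (-3.59 ± 0.71), pentraxin (-2.6 ± 0.5), PLAC8-like protein 1 (-1.13 ± 0.2) and cysteine-rich protein 1 (-1.09 ± 0.18) fell. Hepatocyte markers (8 genes, adjusted p = 0.000531) and acute phase and complement (19 genes, adjusted p = 2.02e-05) were lower, with 4 and 8 falls adjusted over the list alone. For hepatocyte markers p was 1.38e-05 to 0.43 over alternatives (adjusted p = 0.43 with estimated correlation). For acute phase and complement p was 5.88e-06 to 0.224 over alternatives (adjusted p = 0.224 with estimated correlation). Gluconeogenesis and amino acid catabolism (16 genes, adjusted p = 0.00454), collagen and extracellular matrix (11 genes, adjusted p = 0.00814) and proteasome (20 genes, adjusted p = 0.0096) were shifted down, with 1, 5 and 0 falls adjusted over the list alone. For gluconeogenesis and amino acid catabolism p was 0.000483 to 0.277 over alternatives (adjusted p = 0.277 with estimated correlation). For collagen and extracellular matrix p was 0.000522 to 0.445 over alternatives (adjusted p = 0.445 with estimated correlation). For proteasome p was 0.00116 to 0.464 over alternatives (adjusted p = 0.464 with estimated correlation). Antioxidant defence (32 genes, adjusted p = 0.0143), glycolysis (20 genes, adjusted p = 0.0317) and keratins and mucus (13 genes, adjusted p = 0.047) were shifted down, with 2 falls each adjusted over the list alone and adjusted p of 0.0526, 0.0723 and 0.127 with scan day as a block. For antioxidant defence p was 0.00213 to 0.44 over alternatives (adjusted p = 0.44 with estimated correlation). For glycolysis p was 0.00292 to 0.568 over alternatives (adjusted p = 0.568 with estimated correlation). For keratins and mucus p was 0.00596 to 0.627 over alternatives (adjusted p = 0.627 with estimated correlation). Lymphocyte and myeloid markers were lower (28 genes, adjusted p = 0.0205) and neuron markers higher (10 genes, adjusted p = 0.0332), with 1 fall and 1 rise adjusted over the list alone. For lymphocyte and myeloid markers p was 0.00271 to 0.406 over alternatives (adjusted p = 0.406 with estimated correlation). For neuron markers p was 0.00224 to 0.568 over alternatives (adjusted p = 0.568 with estimated correlation). No member of these 10 lists passed over all probes. In all 74 probes passed, 50 up and 24 down, for 15 named genes. The split was 9 up and 8 down in the authors' table, 17 and 57 in the fit of 48 arrays and 2 and 11 there with slide as a fixed block. The count was 0 without medium 4 (limma), 2 without medium 3, 6 in a fit of the 8 arrays, 11 with no filter on dim probes and 157 with slide as a random block.

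Between 8 and 32 ppth in the rosette 621 probes passed, 314 higher and 307 lower at 32 ppth. The count was 942 with scan day as a block, 43 in the fit of 48 arrays, 14 without high 10, and 0 in the fit of 48 with slide as a fixed block (limma, 5534 at unadjusted p under 0.05 in the fit reported). The trend passed for 2 probes, named after their values were seen: very long-chain acyl-CoA synthetase, an enzyme of fatty acid activation, with a slope of 0.0444 ± 0.00489 per ppth, and the unnamed probe A_05_P481112, with 0.0425 ± 0.00486. The trend split was 9 up and 69 down in the fit of 48 arrays, 0 and 3 there with slide as a fixed block, 14 and 15 with the order of the groups and 7 and 1 in the authors' table. Rosette lists that did not pass at any salinity were cholesterol synthesis, erythrocyte markers (lowest adjusted p 0.172, at 32 ppth), fatty acid and lipid metabolism, glucocorticoid-responsive genes, heat shock, hormone receptors and IGF axis, muscle markers, olfactory signalling, osmotic stress, oxidative phosphorylation, ribosomal proteins, seawater ion secretion and tight junctions. Over all tissues 52 list results passed, 17 up and 35 down, none of them with an estimated correlation (camera, 69 at unadjusted p under 0.05 with the preset correlation). With the arrays relabelled 2 to 36 passed, so many of the 52 may be chance.

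The 32 ppth response differed between gill and liver for 97 probes, with 67 higher and 30 lower in gill. Glycogenin-1 differed by -2.28 ± 0.31 (-1.71 in gill, 0.57 in liver), phospho1 by -2.31 ± 0.52, the transporter ABCG2 by -1.72 ± 0.41, chemotaxin by 2.65 ± 0.54 (0.55 in gill, -2.1 in liver), the chaperone clusterin-1 by 2.54 ± 0.52 and ribosomal protein L32 by 2.41 ± 0.53. Gill and rosette differed for 33 probes, 20 higher and 13 lower in gill, including ADP-ribosylation factor 4 (-5.53 ± 0.97, with -2.84 in gill and 2.69 in rosette), phospho1 (-3.01 ± 0.52), RNF128 (-2.37 ± 0.47), the venom-lectin relative nattectin (3.21 ± 0.47), complement factor H (3.11 ± 0.65) and secreted phosphoprotein 24 (4.44 ± 0.98). Liver and rosette differed for 220 probes, 86 higher and 134 lower in liver, against 100 and 97 by quantile normalization, 41 and 31 with no filter on dim probes and 78 and 55 by differences per fish. Among these were liver-type fatty acid-binding protein (5.47 ± 1.14), plasminogen, secreted phosphoprotein 24 (5.04 ± 0.98), clusterin-1 (-2.53 ± 0.53), protein kinase C substrate 80K-H (-1.84 ± 0.44) and ribosomal protein L38 (-1.59 ± 0.36). By differences per fish 11, 71 and 133 passed for the 3 pairs, and 8, 13 and 36 with slide as a fixed block beside fish. The pooled fit gave liver 776 at 32 ppth (28 alone), gill 120 (119) and rosette 113 (133). Other splits gave as many for gill and liver, so chance can too.

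**Figure D3:**
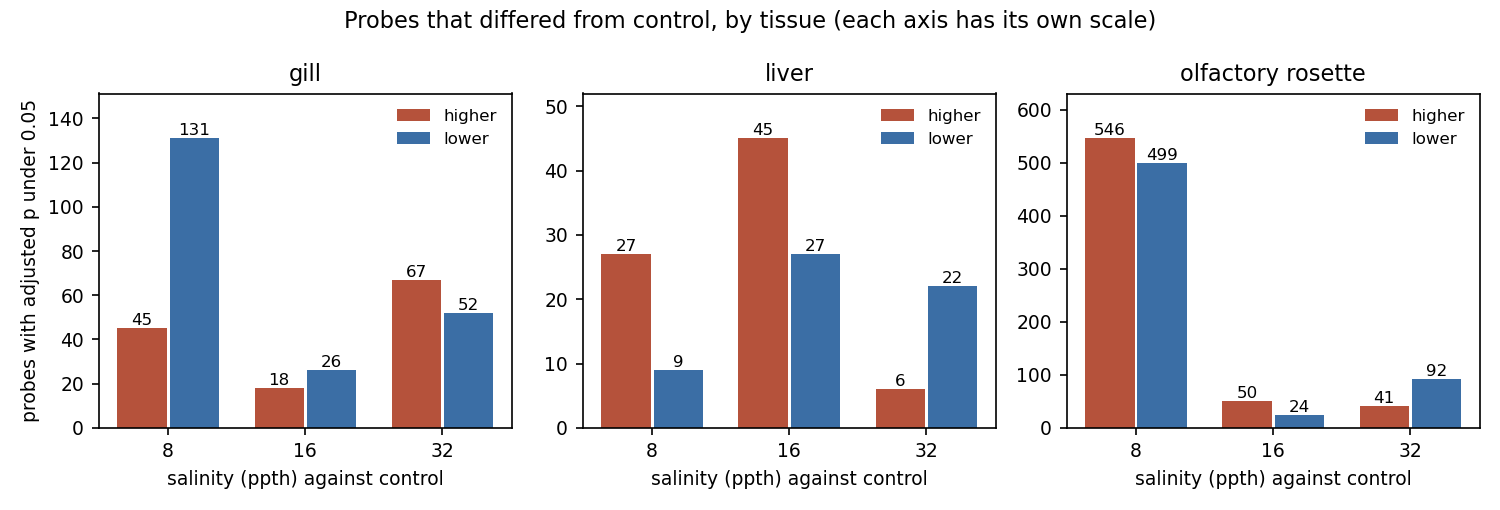
Number of probes past an adjusted p of 0.05 at 8, 16 and 32 ppth against control, as bars from 0 for probes higher and lower than control, each tissue on its own scale. The largest total is 1045, in the olfactory rosette at 8 ppth, and the smallest is 28, in liver at 32 ppth.

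Across salinities, probes past the limit in the same direction numbered 20 (8 and 16 ppth), 24 (8 and 32) and 37 (16 and 32) in gill, 12, 4 and 13 in liver, and 58, 85 and 24 in rosette, and 0 had opposite directions. In gill these included CFTR I and isoform 1a of the Na/K-ATPase alpha subunit, which passed at each salinity. The 4 liver probes shared by 8 and 32 ppth, named after their values were seen, were SLC38A2 on 2 probes, protein kinase C substrate 80K-H and the unnamed probe A_05_P468102. The contrasts share their control arrays, and with the controls split 2 and 2 the mean numbers were 5.5, 8.5 and 14.8 in gill, 0.3, 0.3 and 0.5 in liver and 2.7, 4.2 and 0.8 in rosette.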

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

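The tests weighed here were chosen after the result was seen, except the count of liver-abundant probes in the rosette, whose bounds were fixed before that count was computed but after related values, the hepatocyte marker means among them, had been seen. Groups of 4 arrays were examined for 1 value far from the other 3, and 16 of 207 groups passed, where chance gives about 1 in 20.

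Liver-abundant transcripts were lower in the rosette at 32 ppth, where the median level of the 100 most liver-abundant probes was 0.0373 ± 0.00549% of their level in liver, against 0.21 ± 0.126% in control (SD, n = 4 each). Of these 100 probes 82 were lower, between the bound of 95 set for liver RNA in the control samples and the bound of 80 against it, so carry-over of liver RNA and a change in the rosette itself cannot be told apart by this test. Scaling of the arrays is argued against, since the median change of the hepatocyte markers was -3.47 by quantile normalization. Liver RNA may have entered the control samples at dissection, and at 8 and 16 ppth 84 and 92 of the probes were lower. A biological change with salinity stays open and was not tested.

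Preproinsulin 2 was well above background on 4 of 4 gill arrays at 32 ppth and on no other array. Islet cells in those samples stay open. Preproinsulin 1, somatostatin-1A and glucagon-2 were well above background on 0 of 12 readings there, but only 1 of these 3 probes, that of somatostatin-1A, was so on 4 or more other arrays. The 4 arrays lay on 4 slides and 3 scan days, so no 1 slide or day sets them apart. That 0 of 12 other arrays there detected it restates the pattern. Preparation of the 32 ppth gill RNA could still account for it, as could induction by salinity, and neither was tested.

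More probes passed in the rosette at 8 ppth than at 16 or 32 ppth. With scan day as a block 1332 passed at 8 ppth against at most 86, and without probes brighter in liver 885 against 30, so neither is likely the whole cause. With slide as a fixed block 241 passed against 74, but 0 for 32 against 8 ppth (43 without slide). The pattern depends on the fit, with 0, 6 and 72 at 8, 16 and 32 ppth in fits of 8 arrays and 178, 74 and 113 in the fit of 48. Slide and an untested biological difference stay open.

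The share of spots well above background was far from its group for gill high 8 (gap 0.831 of the range, 47.9% against a mean of 66.93%), gill control 7 (0.926, 36.2% against 69.73%) and liver control 7 (0.888, 30.4% against 47.83%). In gill the fish far from its group was control 9 for RNF128 (0.856), high 9 for RASD1 (0.883), control 7 for preproinsulin 2 (0.891, 0 of 4 well above background), medium 10 for FXYD 11b (0.906) and high 7 for vacuolar proton pump subunit D (0.885). In liver it was low 7 for calumenin (0.845) and medium 3 for calpain 1 (0.873). In rosette it was control 7 for ADP-ribosylation factor 4 (0.835), medium 10 for C-type lectin receptor B (0.843), medium 4 for PLAC8-like protein 1 (0.857), control 3 for cysteine-rich protein 1 (0.883), control 3 for TSC22D3 (0.965) and high 8 for gastrulation-specific protein G12 (0.872).

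In the pooled fit the 32 ppth response differed for 97 probes between gill and liver, 33 between gill and rosette and 220 between liver and rosette. Gill minus liver was 2.65 for chemotaxin, 2.54 for clusterin-1, 2.41 for ribosomal protein L32, -2.31 for phospho1, -2.28 for glycogenin-1 and -1.72 for ABCG2. Gill minus rosette was 4.44 for secreted phosphoprotein 24, 3.21 for nattectin, 3.11 for complement factor H, -5.53 for ADP-ribosylation factor 4, -3.01 for phospho1 and -2.37 for RNF128. Liver minus rosette was 5.47 for liver-type fatty acid-binding protein, 5.33 for plasminogen (inexact, since 0 of 4 rosette arrays at 32 ppth were well above background), 5.04 for secreted phosphoprotein 24, -2.53 for clusterin-1, -1.84 for protein kinase C substrate 80K-H and -1.59 for ribosomal protein L38.

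Other splits of the same arrays were fitted for each count. Only the real split of 35 gave as many in gill at 8 ppth (176, highest other 116), 16 ppth (44, highest other 0), 32 ppth (119, highest other 1) and 32 against 8 ppth (228, highest other 91). As 1 of 35 is the least possible, chance stays open. The same held in liver at 8 ppth (36, highest other 1), 16 ppth (72, highest other 2), 32 ppth (28, highest other 1) and 32 against 8 ppth (4, highest other 1), and in rosette at 8 ppth (1045, highest other 8), 16 ppth (74, highest other 2), 32 ppth (133, highest other 2) and 32 against 8 ppth (621, highest other 1). Of 100 relabellings 1, the real one, gave as many for the gill trend (69, next 57), the rosette trend (2, next 1) and the list results (52, others 2 to 36, so some may be chance). For the liver trend 100 of 100 did (highest 3), as they must with 0 probes, so this decides nothing. For tissue differences missing spots were filled in, which gave 96, 33 and 218 real probes against the 97, 33 and 220 reported. The real count was highest for gill against rosette (33, next 1) and liver against rosette (218, next 9). For gill against liver 3 of 35 splits gave 96 or more, with 416 and 102 in the others, so that count is within reach of chance. In the split with 102, all 4 liver arrays of 1 side were scanned on 1 day, but in the split with 416 at most 3 of a side were. What the latter follows is not known. With scan day as a block beside fish 160 probes passed.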

How the results depend on the processing

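The alternatives that treat scan day as a block, take the percentile over detected probes, leave out arrays under 40% or leave out probes brighter in liver were chosen after seeing the data, and all others before. The gill changes of CFTR I and of isoforms 1a and 1b of the Na/K-ATPase alpha subunit at 32 ppth kept their direction under every alternative run. Of 125 named gene values that passed, 106 stayed past the limit by quantile normalization, 92 by normexp with quantile normalization, 82 in the authors' table, 117 with slide as a random block and 90 with scan day as a block. With array weights 20 no longer passed, and 0 of the 125 reversed in any of these. Sizes depended on the scaling. The median ratio of a change to the one reported was 0.66 in the authors' table (63 of 125 were smaller by over 1.5 times) and 0.7 by normexp with quantile normalization (55 of 125), whose offset of 50 draws weak signals together. Of 2000 values with 1 array left out, 1375 stayed past the limit. Of 52 list results, 40 stayed past the limit by quantile normalization, 42 in the authors' table, 43 with slide as a random block, 43 with scan day as a block, 44 with the mean of a gene's probes and 45 without the dim arrays, against 15 with fry and 0 with an estimated correlation. Signal over background limits the results most in liver, where the mean share of spots well above background was 47.4%, and weak transcripts there were not detectable on all 4 arrays of a group. With 4 arrays per group, simulated 1.5-fold changes were recovered for 5.97% of probes in gill at 32 ppth, so small changes were mostly out of reach.

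Counts that moved by over 1.5 times follow by alternative, and the cause was not tested unless named. Fits of 8 arrays and with the fish number as block leave fewer residual degrees of freedom, and the alternatives on dim probes and liver-brighter probes change the number of probes tested. By normexp with quantile normalization the count was 274 for gill 8 ppth, 11 for liver 8 ppth, 122 for liver 16 ppth, 1 for liver 32 against 8 ppth. In rosette 32 ppth it was 75, with 5 for rosette trend, 149 for gill against liver, 113 for gill against rosette. In the authors' table the count was 281 for gill 8 ppth, 14 for liver 8 ppth, 124 for liver 16 ppth, 1 for liver 32 against 8 ppth. In rosette 16 ppth it was 17, with 52 for rosette 32 ppth, 8 for rosette trend. For gill against liver it was 147, with 129 for gill against rosette. In liver shared by 8 and 16 ppth it was 6, with 2 for liver shared by 8 and 32 ppth, 14 for rosette shared by 8 and 16 ppth, 35 for rosette shared by 8 and 32 ppth, 6 for rosette shared by 16 and 32 ppth. With no filter on dim probes the count was 84 for gill 8 ppth, 118 for gill 32 against 8 ppth. In liver 8 ppth it was 0, with 22 for liver 16 ppth, 14 for liver 32 ppth. For rosette 8 ppth it was 609, with 11 for rosette 16 ppth, 309 for rosette 32 against 8 ppth. In gill against liver it was 46, with 72 for liver against rosette. On probes well above background on all 16 arrays the count was 359 for gill 8 ppth, 70 for liver 8 ppth, 12 for liver 32 against 8 ppth, 14 for liver trend. In rosette 16 ppth it was 49, with 42 for rosette 32 ppth, 4 for rosette trend. With array weights the count was 67 for gill 8 ppth, 353 for gill 32 against 8 ppth. In liver 8 ppth it was 273, with 26 for liver 16 ppth, 197 for liver 32 against 8 ppth. For rosette 16 ppth it was 149, with 1644 for rosette 32 against 8 ppth, 11 for rosette trend. With no intensity trend the count was 89 for gill 8 ppth, 141 for gill 32 against 8 ppth. For liver 8 ppth it was 0, with 37 for liver 16 ppth, 16 for liver 32 ppth, 34 for rosette 16 ppth. With slide as a fixed block in a fit of 48 arrays the count was 97 for gill 8 ppth, 15 for gill 16 ppth, 65 for gill 32 ppth, 114 for gill 32 against 8 ppth. For liver 8 ppth it was 1126, with 275 for liver 16 ppth, 336 for liver 32 ppth, 436 for liver 32 against 8 ppth, 67 for liver trend. In rosette 8 ppth it was 241, with 13 for rosette 16 ppth, 74 for rosette 32 ppth, 0 for rosette 32 against 8 ppth. In the fit of 48 arrays with fish as a random block the count was 270 for gill 8 ppth. In liver 8 ppth it was 928, with 1227 for liver 16 ppth, 776 for liver 32 ppth, 720 for liver 32 against 8 ppth, 556 for liver trend. For rosette 8 ppth it was 178, with 43 for rosette 32 against 8 ppth, 78 for rosette trend. With the percentile over probes detected on all 16 arrays the count was 288 for gill 8 ppth, 129 for liver 16 ppth, 0 for liver 32 against 8 ppth, 4 for liver trend. For rosette 16 ppth it was 117, with 4 for rosette trend. Without arrays under 40% the count was 57 for gill 8 ppth, 63 for liver 8 ppth, 9 for liver 32 ppth, 0 for liver 32 against 8 ppth. In a fit of only the 8 arrays compared the count was 2 for gill 8 ppth, 14 for gill 16 ppth, 40 for gill 32 ppth, 22 for gill 32 against 8 ppth. In liver 8 ppth it was 0, with 0 for liver 16 ppth, liver 32 ppth and liver 32 against 8 ppth. For rosette 8 ppth it was 0, with 6 for rosette 16 ppth, 72 for rosette 32 ppth. With scan day as a block the count was 130 for gill 32 against 8 ppth, 0 for liver 8 ppth and liver 32 against 8 ppth. For rosette 32 ppth it was 86, with 942 for rosette 32 against 8 ppth. With slide as a random block the count was 163 for liver 8 ppth, 49 for liver 32 against 8 ppth, 5 for liver trend. For rosette 8 ppth it was 3397, with 157 for rosette 16 ppth, 967 for rosette 32 against 8 ppth. By quantile normalization the count was 0 for liver 32 against 8 ppth, 7 for liver trend, 52 for gill against rosette. With the order of the groups in place of ppth the count was 16 for liver trend, 29 for rosette trend. Without probes 16-fold brighter in liver the count was 30 for rosette 16 ppth, 18 for rosette 32 ppth. With one value per gene the count was 5 for rosette trend. For gill against liver, gill against rosette and liver against rosette, 8, 13 and 36 passed with slide as a fixed block beside fish. By tissue differences per fish 11, 71 and 133 did. With scan day as a block beside fish the count was 160 for gill against liver, 609 for liver against rosette. For list results the count was 0 with an estimated correlation and 15 with fry in place of camera. With the controls split 2 and 2 the counts shared by 8 and 16 ppth, 8 and 32 ppth, and 16 and 32 ppth follow. They were 5.5, 8.5 and 14.8 in gill, 0.3, 0.3 and 0.5 in liver and 2.7, 4.2 and 0.8 in rosette.

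Values that changed sign were all of genes that had not passed, and the cause was not tested. Metallothionein B in gill at 32 ppth was 0.00 in the authors' table and 0.04 with array weights. The sodium/potassium ATPase subunit beta-233 in gill at 8 ppth was -0.06 with slide as a random block. Vacuolar proton pump subunit D in gill at 8 ppth was 0.06 by quantile normalization, 0.07 by normexp, 0.08 in the authors' table, 0.01 with slide as a random block, 0.02 with array weights and 0.00 with scan day as a block, and at 16 ppth 0.00 with array weights. With 1 array left out, gill values that changed sign ranged over -0.14 to 0.12 for metallothionein B at 32 ppth (-0.06 with all arrays), -0.21 to 0.53 for DDIT4-like at 32 ppth (0.19 with all arrays), -0.23 to 0.45 for beta-233 at 8 ppth (0.06 with all arrays), -0.13 to 0.25 for CFTR II at 8 ppth (0.02 with all arrays), -0.01 to 0.24 for FXYD 11b at 32 ppth (0.09 with all arrays), -0.05 to 0.02 for vacuolar proton pump subunit D at 8 ppth (-0.01 with all arrays), -0.3 to 0.11 for Na/H exchanger 8 at 8 ppth (-0.16 with all arrays).

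Fish numbers were tested as a pairing of arrays across salinities. After removing group means, arrays with the same number correlated by a mean of 0.084 in gill (range -0.195 to 0.35). In liver it was -0.027 and in rosette 0.012, over 9 pairs each, too few to exclude a pairing. The block is an alternative only, with 4 residual degrees of freedom. With the fish number as block the count was 2 for gill 8 ppth and gill 16 ppth, 3 for gill 32 ppth and gill 32 against 8 ppth, 0 for gill trend. In liver 8 ppth it was 0, with 0 for liver 16 ppth, liver 32 ppth and liver 32 against 8 ppth. In rosette 8 ppth it was 0, with 0 for rosette 16 ppth, rosette 32 against 8 ppth and rosette trend, 1 for rosette 32 ppth. In list results it was 34. With this block DDIT4-like in gill at 32 ppth was -0.16, taurine transporter in liver at 16 ppth -0.07, CFTR II in gill at 8 ppth -0.29 and carbonic anhydrase 12 in gill at 8 ppth -0.52, none past the limit, and 1 of 125 named gene values stayed past it.

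The lowest and highest counts with 1 array left out, or 1 fish for tissue differences, follow. They were 57 to 213 for gill 8 ppth, 24 to 58 for gill 16 ppth, 62 to 158 for gill 32 ppth. Counts ran from 66 to 326 for gill 32 against 8 ppth, 45 to 78 for gill trend, 0 to 90 for liver 8 ppth. They were 8 to 97 for liver 16 ppth, 3 to 37 for liver 32 ppth, 0 to 8 for liver 32 against 8 ppth. Counts ran from 0 to 16 for liver trend, 307 to 1896 for rosette 8 ppth, 0 to 92 for rosette 16 ppth. They were 62 to 133 for rosette 32 ppth, 14 to 1416 for rosette 32 against 8 ppth, 2 to 16 for rosette trend. Counts ran from 23 to 171 for gill against liver, 21 to 34 for gill against rosette, 58 to 380 for liver against rosette. They were 45 to 55 for list results, 14 to 26 for gill shared by 8 and 16 ppth, 15 to 41 for gill shared by 8 and 32 ppth. Counts ran from 24 to 40 for gill shared by 16 and 32 ppth, 0 to 25 for liver shared by 8 and 16 ppth, 0 to 16 for liver shared by 8 and 32 ppth. They were 1 to 19 for liver shared by 16 and 32 ppth, 0 to 70 for rosette shared by 8 and 16 ppth, 40 to 74 for rosette shared by 8 and 32 ppth. Counts ran from 0 to 22 for rosette shared by 16 and 32 ppth.

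Each array, or fish, whose absence moved a count by over 1.5 times is named by salinity and number. Gill 8 ppth had 86 without medium 9, 116 without high 8, 26 up and 79 down without low 2, 57 without control 7, 73 without low 6, 68 without control 6. It had 99 without medium 10, 60 without low 5, 115 without medium 4, 80 without low 7. Gill 16 ppth had 24 without medium 3. Gill 32 ppth had 75 without high 9, 62 without high 8, 63 without control 6. Gill 32 against 8 ppth had 139 without medium 9 or low 5, 76 without high 9, 66 without high 8, 104 without low 2, 74 without low 6, 111 without high 7. It had 90 without low 7. Gill trend had 45 without high 8. Liver 8 ppth had 18 without medium 9, 0 without high 10 or low 6 or low 5 or high 8 or medium 4 or control 9 or low 2 or control 3 or low 7, 13 without medium 3, 6 without high 9 or high 7, 90 without control 7. Liver 16 ppth had 10 without medium 9, 27 without high 10, 26 without low 6, 47 without medium 10, 8 without control 6, 32 without low 5. It had 44 without high 9 or high 8, 14 without medium 4, 46 without high 7, 13 without control 9, 34 without low 2, 40 without control 3. Liver 32 ppth had 18 without medium 9, 4 without high 10, 17 without low 6, 7 without control 6, 16 without low 5, 3 without high 7. It had 13 without control 9 or low 7. Liver 32 against 8 ppth had 0 without high 10 or low 6 or high 7 or low 2 or low 7, 8 without high 9. Liver trend had 16 without high 8, 3 without control 9, 5 without control 3. Rosette 8 ppth had 307 without low 5, 541 without control 6, 489 without control 3, 586 without low 7, 521 without control 9, 608 without low 6. It had 1896 without control 7, 359 without low 2. Rosette 16 ppth had 24 without control 6, 8 without low 7 or medium 9, 19 without control 9, 26 without low 6 or low 2, 12 without high 10, 0 without medium 4. It had 2 without medium 3, 13 without high 9, 9 without medium 10. Rosette 32 ppth had 62 without high 10 or high 9, 69 without high 8, 64 without high 7. Rosette 32 against 8 ppth had 85 without low 5, 253 without low 7, 206 without low 6 or high 9, 14 without high 10, 1416 without control 7, 189 without low 2. It had 275 without high 8, 157 without high 7. Rosette trend had 4 without control 6, 13 without control 3, 7 without control 9, 16 without low 2, 6 without medium 10. Gill against liver had 23 without high 10 or high 7, 162 without control 3, 31 without control 6, 171 without high 9, 64 without high 8. Gill against rosette had 21 without high 7. Liver against rosette had 71 without high 10, 127 without control 3, 380 without high 9, 121 without high 8, 58 without high 7. Gill shared by 8 and 32 ppth had 41 without control 3, 15 without control 7 or control 6 or low 5. Gill shared by 16 and 32 ppth had 24 without medium 3. Liver shared by 8 and 16 ppth had 3 without medium 9, 0 without low 6 or low 5 or medium 4 or control 9 or low 2 or control 3 or low 7, 5 without medium 3, 7 without medium 10, 1 without control 6, 25 without control 7. Liver shared by 8 and 32 ppth had 0 without high 10 or low 6 or low 5 or high 8 or high 7 or control 9 or low 2 or control 3 or low 7, 1 without control 6 or high 9, 16 without control 7. Liver shared by 16 and 32 ppth had 5 without medium 9, 1 without high 10 or high 7, 8 without medium 10, 3 without control 6, 7 without high 9, 6 without medium 4. It had 4 without control 9. Rosette shared by 8 and 16 ppth had 19 without control 6, 6 without low 7 or medium 9, 18 without control 9, 20 without low 6, 0 without medium 4, 1 without medium 3. It had 16 without low 2, 8 without medium 10. Rosette shared by 8 and 32 ppth had 50 without control 6 or control 3 or high 8, 53 without low 6, 40 without high 10, 45 without low 2, 44 without high 9 or high 7. Rosette shared by 16 and 32 ppth had 7 without control 6, 12 without control 9, 6 without high 10 or high 9, 0 without medium 4, 1 without medium 3, 4 without medium 9. It had 14 without high 8, 3 without medium 10, 13 without high 7.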

Other observations

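Of 639 probes at least 16-fold brighter on the liver arrays than in gill, 299 were lower in gill at 8 ppth (median change 0.02), 358 at 16 ppth (-0.04) and 391 at 32 ppth (-0.1). At these salinities 6, 2 and 5 of them fell past the limit, and 0, 0 and 1 rose.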
